A study of Mus musculus with 6 samples.

How the data were processed

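RNA from whole-brain homogenates of 6 mouse samples, 3 wild-type (WT) and 3 carrying SOD1-G85R, was measured on a NanoString panel of 770 genes. NanoString counts colour-coded probes hybridised to RNA without amplification, and the labels' protocols describe homogenisation with beads, proteinase K digestion, lysis and RNA extraction. The deposited table holds 1 signal value per gene and sample, called a normalized count below. The software, the genes behind the scaling and any background rule are not given in the sources used here, and control probes were not used here.

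The form of the deposited signal was read from its values. In every sample the values above the sample's lowest value and below 150 were whole multiples of 1 step, with 100% of them whole within 0.1 count. The step, which is what 1 count is worth in that sample, was 0.791, 1.01 and 0.799 in WT replicates 1, 2 and 3 and 1.07, 0.796 and 1.42 in SOD1-G85R replicates 1, 2 and 3. The lowest value was shared by 54, 59 and 29 genes in WT replicates 1, 2 and 3. In SOD1-G85R replicates 1, 2 and 3 it was shared by 10, 13 and 19 genes, fewer than in any WT sample. The lowest value of each sample was therefore read as a floor set by the authors. In 5 of the 6 samples it was also no whole multiple of the step within 0.1 count, while in WT replicate 3 it was 10.1 steps, which is whole within that tolerance. Floors were 8.87, 13.4 and 8.05 in WT and 7.85, 11.4 and 10.2 in SOD1-G85R. A value at the floor gives only an upper limit. Because of the floor, tests made for raw counts were not used. Fold changes of genes near the floor are compressed, and a scaling step that differs between samples moves them. Dividing the summed values by the step gave implied total counts of 857918, 689721 and 970312 in WT and 551726, 1022670 and 468718 in SOD1-G85R.

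The samples were grouped by the genotype in the labels. The deposited scaling was kept, and values were taken as log2(value + 1), a scale that understates the change of low genes. Genes above 20 in at least 3 of the 6 samples were tested, which kept 712 and left out 58. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Means ± SD are of the normalized counts, and log2 fold changes (SOD1-G85R minus WT) are on the log2(value + 1) scale with limma's standard error. Of 31 gene lists, 23 had at least 5 measured members and were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. The other 8 were too small, among them the lists of ALS-linked genes with 2 measured members, of mitochondrial respiration with 2 and of cholinergic and motor neuron genes with 0. Camera with an estimated correlation and fry were alternatives.

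The groups, the main test, the filter, the lists, the rule for named genes and the first set of other settings were fixed before the data were examined. The rule took Sod1, then up to 12 genes per direction past the threshold. With fewer than 20 passing, it filled up to 20 with the genes of smallest unadjusted p whose groups did not overlap, and allowed the 3 members of smallest p of each tested list. Genes named outside this rule are said to be so, and some that it allows are not reported here. Sod1 was not analysed here, so the genotype labels were not checked against the transgene and no other setting was run for it.

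The other settings fixed then were leaving out each replicate, centring on the median or on the housekeeping genes, quantile normalization, no filter or a filter at 50, pseudocounts of 0.5 and 10, the replicate number as a block, a trended robust variance, sample weights and other thresholds. A term for Uty signal, a common floor of 20 and further fits without SOD1-G85R replicate 2 were added after seeing the data. The fit was tested on simulated values with the spread of the real ones over 712 genes. With all 6 samples it recovered 56% of genes changed by 1 on the log2 scale and 89% of those changed by 2, with 3 false calls. Without SOD1-G85R replicate 2 it recovered 81% and 100%, with 8 false calls. The simulated genes were independent, had the same spread in every sample and had no floor. These shares need not hold for real genes that vary together or with 1 sample that stands apart. No pair of samples agreed within counting noise, the lowest chi-square per degree of freedom on the implied counts being 24.2. Of the 770 gene symbols, 763 were current and 7 were synonyms in the GRCm38.p6 annotation, which was used for names only. Figures were drawn with matplotlib 3.10.9.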

Results

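Whole-brain RNA from WT mice and from mice transgenic for SOD1-G85R, all on a C57BL/6 background and labelled day 10, was compared on a 770-gene panel. SOD1-G85R is a mutant superoxide dismutase 1 linked to amyotrophic lateral sclerosis, and the series set out to profile expression in this mouse model. Each genotype had 3 samples. The labels do not say from when the days were counted or whether all replicates were separate animals, so p-values measure only the spread between these samples. Implied total counts ranged from 689721 to 970312 in WT and from 468718 to 1022670 in SOD1-G85R. The Y-linked genes Uty and Kdm5d gave signal in WT replicates 1 and 2 and in SOD1-G85R replicate 2 only, so that 2 WT samples and 1 SOD1-G85R sample carried it and neither group came from a single animal. SOD1-G85R replicate 2 stood apart from the other 5 samples, with log2 correlations across genes of 0.824 to 0.834 against 0.956 to 0.984 among the others. Genes are not independent replicates for such correlations.

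Myelin and oligodendrocyte genes fell as a group in SOD1-G85R brain. Opalin, a membrane protein of mature oligodendrocytes, averaged 608 ± 106 normalized counts in WT and 178 ± 31.9 in SOD1-G85R (SD, n = 3 each), a log2 fold change of -1.77 (SE 0.23). Mag, the myelin-associated glycoprotein, averaged 1630 ± 308 and 865 ± 180, a log2 fold change of -0.92 (SE 0.26). Of the 24 measured members of the list, 23 had a negative fold change, and the median was -0.71 (camera, adjusted p = 1.97e-13, and adjusted p = 0.413 with an estimated correlation). The list's median against the WT mean was -1.17, -0.49 and -0.47 in the SOD1-G85R samples and between -0.30 and 0.23 in the WT samples. No member passed limma's threshold over all genes, while 2, Opalin among them, did when adjusted over the list alone, and 13 did so without SOD1-G85R replicate 2.

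Genes of glutamate signalling fell as well. Grin2a, an NMDA receptor subunit, averaged 365 ± 36.2 in WT and 208 ± 17.3 in SOD1-G85R (log2 fold change -0.81, SE 0.18). Slc17a7, the vesicular glutamate transporter VGLUT1, averaged 6022 ± 639 and 3418 ± 866, and the postsynaptic scaffold gene Homer1 averaged 2676 ± 624 and 1549 ± 417. Of 14 measured members 13 had a negative fold change, with a median of -0.37, or -0.58 with samples centred on their medians (camera, adjusted p = 1.40e-05, and adjusted p = 0.413 with an estimated correlation). None passed when adjusted over the list alone. Arc, an activity-regulated synaptic gene, averaged 386 ± 30.2 and 211 ± 25.0 and was the 1 immediate early gene to pass when adjusted over its list alone, in a list that was not called (adjusted p = 0.159). The synaptic scaffold gene Dlg1 averaged 1062 ± 157 and 570 ± 38.9 (log2 fold change -0.89, SE 0.20).

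The pan-neuronal list, with Nefl (neurofilament light chain) at 2456 ± 384 in WT and 1639 ± 173 in SOD1-G85R, fell with a median of -0.27 over 11 members, 7 lower and 4 higher (camera, adjusted p = 0.0323, and adjusted p = 0.413 with an estimated correlation). The cytoskeleton list, which shares Nefl and holds the kinase gene Pak1 at 6010 ± 121 and 4049 ± 337, fell with a median of -0.30 over 10 members, 7 lower and 3 higher (adjusted p = 0.0374, and adjusted p = 0.413 with an estimated correlation). The groups did not overlap in 2 lower and 2 higher members of the pan-neuronal list and in 4 lower and 2 higher members of the cytoskeleton list. Without SOD1-G85R replicate 1 the medians were -0.087 and -0.14, and the pan-neuronal median was -0.11 without WT replicate 2, while centring on sample medians gave -0.48 and -0.50. Both lists missed the threshold without SOD1-G85R replicate 2 (adjusted p = 0.171 and 0.114), without WT replicate 2 (0.0589 each) and after quantile normalization (0.583 each, with a pan-neuronal median of -0.17), and the cytoskeleton list also without WT replicate 1 (0.0919).

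**Figure D1:**
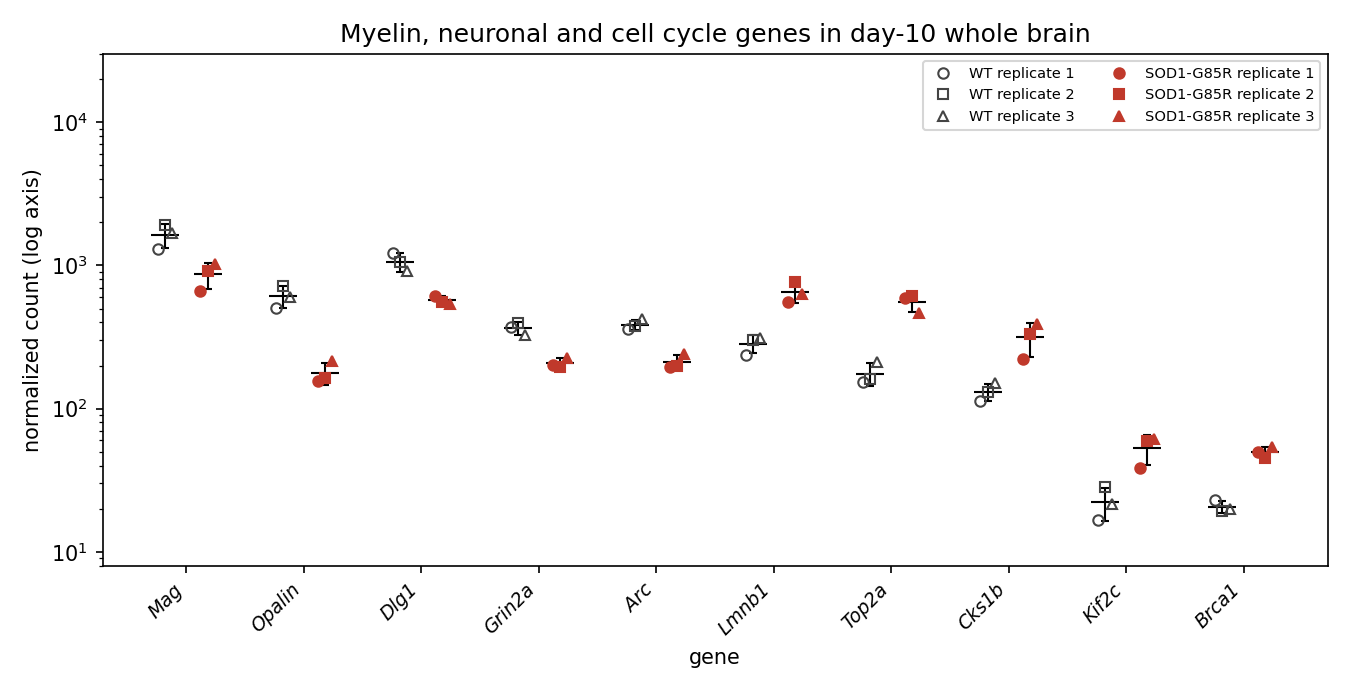
Normalized counts (log axis) of myelin, neuronal and cell cycle genes in each of the 3 WT (open) and 3 SOD1-G85R (filled) samples, with bars for the mean and SD of each group. No gene's groups overlap, but the genes were chosen after the results were seen. The naming rule behind them favours small p and lack of overlap. Opalin runs from 505 to 718 in WT and from 157 to 214 in SOD1-G85R.

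Genes of the cell cycle and DNA damage response rose as a group in the deposited scaling, while under quantile normalization their median was -0.15 and the call was lost. Top2a, the topoisomerase of dividing cells, averaged 176 ± 31.4 in WT and 555 ± 79.9 in SOD1-G85R (log2 fold change 1.66, SE 0.22). Brca1, which acts in DNA repair, averaged 20.7 ± 2.01 and 49.8 ± 4.31 (log2 fold change 1.23, SE 0.18), and the mitotic kinesin gene Kif2c averaged 22.1 ± 5.79 and 53.1 ± 12.7. After quantile normalization the log2 fold change was 1.45 for Top2a and 0.45 each for Brca1 and Kif2c. Brca1 and Kif2c have WT means under 30 and belong to the low-signal genes for which scaling near background stays open, as described below. Of 49 measured members 39 had a positive fold change, 11 of them at an unadjusted p of 0.05 by limma, and the list median was 0.26 (camera, adjusted p = 0.0338, and adjusted p = 0.612 with an estimated correlation). The median of all genes was 0.15 in the deposited scaling, and relative to it the list median was 0.11. The list shares Slfn8 with the interferon list. Top2a and Brca1 passed when adjusted over the list alone. The call was lost without WT replicate 2 (adjusted p = 0.0589), without SOD1-G85R replicate 1 (0.126, with a list median of 0.39) and without SOD1-G85R replicate 3 (0.0892), and with samples centred on their medians (0.183, with a list median of 0.05). Without WT replicate 1 the list median was 0.14. Outside the list, the nuclear lamina gene Lmnb1 averaged 284 ± 40.1 and 653 ± 105, and Cks1b, a partner of cyclin-dependent kinases, averaged 131 ± 18.6 and 315 ± 84.1.

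The apoptosis list rose with a median of 0.30 over 32 members in the deposited scaling (camera, adjusted p = 0.0421, and adjusted p = 0.677 with an estimated correlation). Relative to the median of all genes the list median was 0.15 as deposited. The list median was 0.09 with samples centred on their medians and 0.00045 after quantile normalization, and the call was lost under both (adjusted p = 0.0619 and 0.170). The call was also lost without SOD1-G85R replicate 2 (adjusted p = 0.0791, median 0.19), WT replicate 1 (0.0919) or WT replicate 2 (0.0589). Its leading members were the death receptor genes Tnfrsf10b, at 29.2 ± 7.98 in WT and 66.1 ± 15.2 in SOD1-G85R, and Fas, at 19.8 ± 2.64 and 51.2 ± 20.4. Both have WT means under 30 and belong to the low-signal genes for which scaling near background stays open, as described below.

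Markers of lymphocytes and granulocytes rose as a group at low signal. Tbx21, a T cell transcription factor gene, averaged 10.4 ± 2.64 in WT and 32.2 ± 10.5 in SOD1-G85R, the chemokine gene Xcl1 10.6 ± 2.43 and 34.1 ± 15.7, and the eosinophil marker Siglecf 16.9 ± 1.96 and 43.9 ± 16.7. Of 16 members 15 had a positive fold change and 7 passed when adjusted over the list alone, with a list median of 1.17 (camera, adjusted p = 0.000130, and adjusted p = 0.413 with an estimated correlation). The WT mean was under 30 in 12 of the 16, and Tbx21 and Xcl1 were at the floor in 2 of the 3 WT samples. Both were under 20 in every WT sample, so the filter kept them only because all 3 SOD1-G85R samples exceeded 20. The tally of positive members is thus partly set by the filter. Without the filter the list median was 1.075 (camera at the preset correlation, adjusted p = 4.39e-06). Quantile normalization gave a list median of 0.43 and an adjusted p = 0.185, and setting values under 20 to 20 gave a median of 0.63. Of the other immune genes named by the rule, Cd244 averaged 10.6 ± 2.43 and 41.4 ± 10.1, Trem1 10.9 ± 2.31 and 35.3 ± 15.3, Hcar2 10.9 ± 2.31 and 42.9 ± 22.0 and the macrophage metalloelastase gene Mmp12 10.3 ± 2.77 and 33.8 ± 7.23, each at the floor in 2 WT samples. The cytokine gene Lta averaged 14.8 ± 1.77 and 32.0 ± 0.906, and Lrg1 13.3 ± 2.91 and 32.5 ± 5.16. For these 6 genes, Tbx21 and Xcl1 the log2 fold change was 1.07 to 1.86 as deposited and 0.17 to 0.94 after quantile normalization. These 6 genes were also under 20 in every WT sample and above 20 in every SOD1-G85R sample. The filter would not have kept them otherwise, so their direction is no separate evidence.

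Interferon response genes were high in 1 sample, SOD1-G85R replicate 2. Cxcl10, an interferon-induced chemokine, was at 3511 normalized counts there and at 24.5 and 24.2 in the other SOD1-G85R samples, against a WT mean of 13.3 ± 4.36. Slfn8 was at 708 in that sample against 26.9 ± 2.05 in WT, and Ifitm2, an antiviral membrane protein gene, averaged 424 ± 62.3 in WT and 820 ± 288 in SOD1-G85R. In that sample 17 of 18 measured members lay above all 5 other samples, and the list's median was 4.27 over the WT mean on the log2 scale, against 0.04 and 0.36 in the other SOD1-G85R samples. The list was called higher (median 1.34, camera, adjusted p = 0.0425, and adjusted p = 0.699 with an estimated correlation). Without that sample the median was 0.25 and the call was lost (adjusted p = 0.211), and without SOD1-G85R replicate 1 the median was 2.09. Reactive astrocyte markers were called higher (median 0.81, adjusted p = 0.0425, and adjusted p = 0.677 with an estimated correlation), with Ptx3 at 24.7 ± 4.32 and 94.0 ± 51.2, B3gnt5 at 122 ± 29.7 and 234 ± 24.0 and Cd44 at 30.4 ± 1.08 and 52.9 ± 9.75, but without SOD1-G85R replicate 2 their median was 0.28 and the call was lost (adjusted p = 0.0791). Their median was 0.37 after quantile normalization. Both calls were also lost without WT replicate 2 (adjusted p = 0.0881 and 0.105) and without WT replicate 3 (0.0999 and 0.0601).

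**Figure D2:**
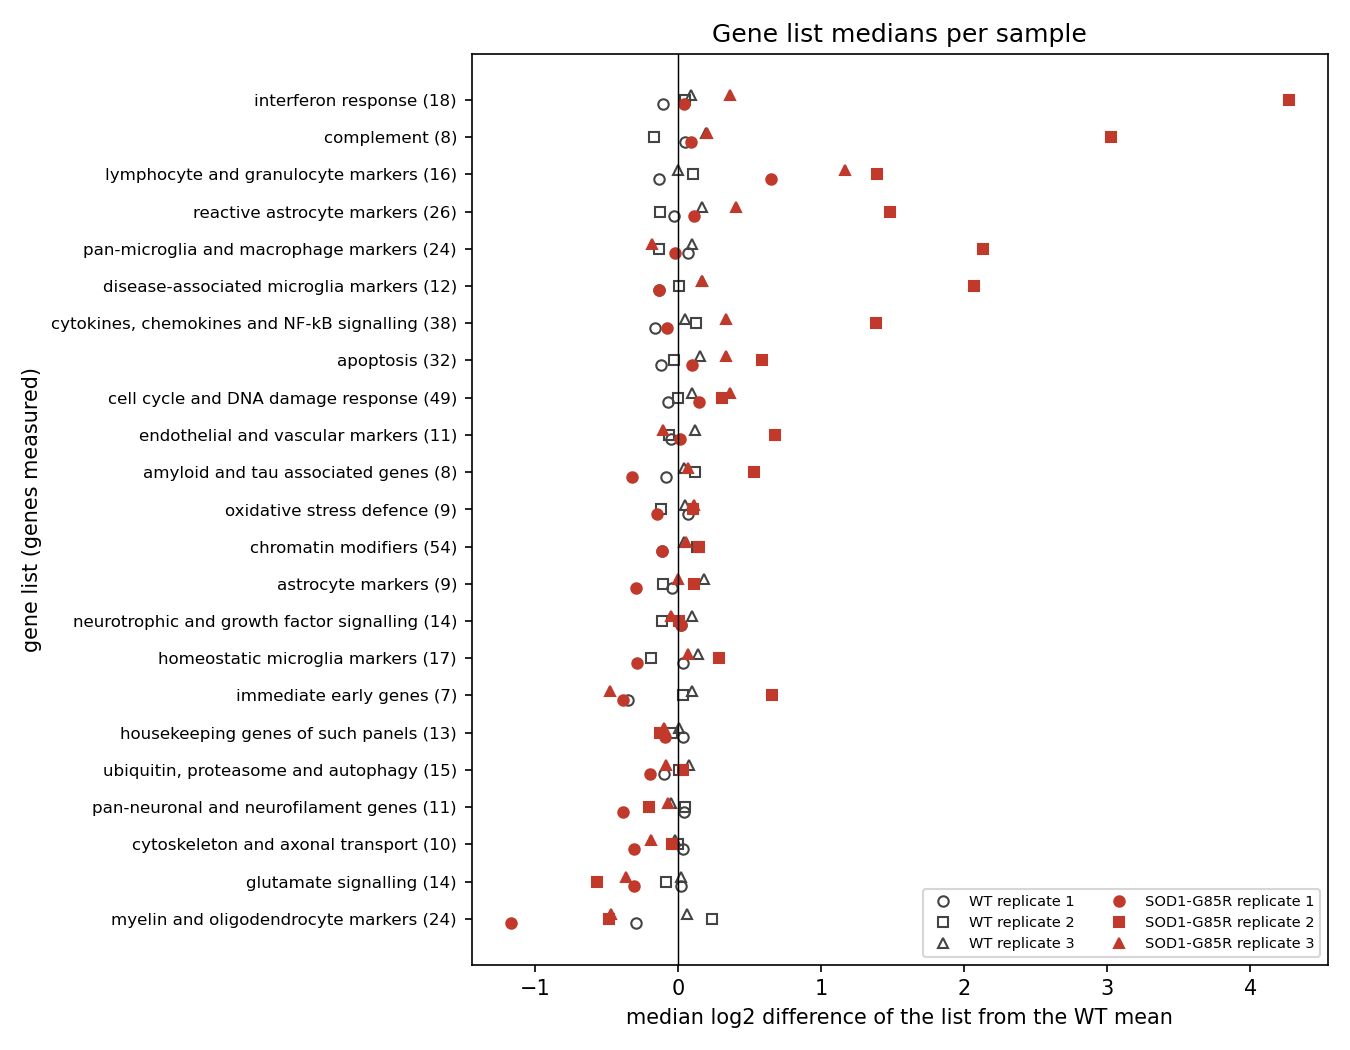
Median log2 difference of each tested gene list from the WT mean (x axis) in each sample, with the number of genes measured in parentheses, WT open and SOD1-G85R filled. SOD1-G85R replicate 2 reaches 4.27 for the interferon list, while all 3 SOD1-G85R samples lie below all WT samples for the myelin list.

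Over the whole panel, limma called 0 of 712 genes at an adjusted p of 0.05, with a smallest adjusted p of 0.0810, so no gene named above passed that test. Without SOD1-G85R replicate 2 it called 10 genes, of which Opalin was lower and Top2a, Brca1, Cd244, Mmp12, Tbx21, Hcar2, Trem1, Ptx3 and Kir3dl2 were higher, the last named after its values were seen. Of these, Cd244, Mmp12, Tbx21, Hcar2, Trem1 and Kir3dl2 were under 20 in every WT sample. The filter kept them only because every SOD1-G85R sample exceeded 20, so their direction is no separate evidence. At an unadjusted p of 0.05 there were 116 genes, 83 higher and 33 lower, or 71.6% higher. That share was 82.8% when samples were centred on housekeeping genes and 37.9% after quantile normalization. The groups did not overlap in 192 genes, or 27.0%, against 10% by chance for 3 samples against 3 without a filter. A gene under 20 in every WT sample passed the filter only if its groups did not overlap, which can raise the share. The share was not computed for other splits, so an excess was not tested. The median log2 fold change over all genes was 0.15 as deposited, -0.06 with samples centred on their medians and -0.08 after quantile normalization, and relative to it the myelin list median was -0.86 as deposited. Between-group distances exceeded within-group distances by 4.16 (exact permutation test, p = 0.1, the smallest that 3 against 3 allows), but with each gene at unit variance the exact p was 0.2.

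Of the 23 lists, 9 were called, 4 lower and 5 higher, and 0 with an estimated correlation or with fry in 1 direction. Other splits of the 6 samples gave up to 12 lists, so that the number of called lists did not stand out. Without SOD1-G85R replicate 2 the myelin, glutamate, lymphocyte and cell cycle lists were called, and 0 with an estimated correlation. The 14 lists that were not called had adjusted p from 0.0885 to 0.719 in the deposited scaling. Of these 14, oxidative stress defence passed with fry in either direction (adjusted p = 0.0246), with 5 members higher and 4 lower. With samples centred on their medians 12 lists were called, and 5 of these 14 were among them: microglia and macrophage markers (adjusted p = 0.0148), complement (0.0149), disease-associated microglia (0.0315) and cytokines (0.0315) higher and chromatin modifiers (0.0303) lower. After quantile normalization 6 were called, among them complement (0.00726) and disease-associated microglia (0.00863). Among them, the median as deposited was 0.74 for microglia and macrophage markers, 1.22 for complement, 0.65 for disease-associated microglia, 0.52 for cytokines and chemokines and 0.19 for endothelial markers. Without SOD1-G85R replicate 2 they were, in the same order, -0.08, 0.26, 0.05, 0.12 and -0.06. The median as deposited was -0.05 for homeostatic microglia, -0.04 for astrocytes, 0.07 for oxidative stress defence, -0.12 for the ubiquitin and autophagy list, -0.05 for growth factor signalling, -0.07 for immediate early genes, 0.01 for chromatin modifiers, 0.07 for amyloid and tau associated genes and -0.11 for housekeeping genes. Without that sample the oxidative stress, chromatin and amyloid and tau medians were -0.08, -0.03 and -0.21, the astrocyte median -0.21 and the immediate early median -0.43.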

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

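The tests of SOD1-G85R replicate 2 in this part were all chosen after its values had been seen, as was the level of 100 normalized counts used to list genes here. The low-value filter left out 58 genes from the comparison, and 14 of them gave over 100 in that sample with no WT sample at that level. They were Ccl5 at 5298, Zbp1 at 1526, Oas1g at 527, Cxcl9 at 507, Tlr2 at 317, Slamf8 at 296, Il1rn at 245, Gzma at 166, Cd300lf at 158, Gzmb at 154, Nkg7 at 148, Klrk1 at 135, Cd3g at 106 and Il21r at 101. Ccl5, Cxcl9 and Zbp1 are interferon- or inflammation-induced, Gzma, Gzmb, Nkg7 and Klrk1 are genes of cytotoxic lymphocytes, and Cd3g is a gene of T cells in general. Ccl5 was at the floor of 7.85 and 10.2 in the other SOD1-G85R samples and at 13.4 or less in WT.

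A scaling or depth error of this sample would move all genes alike, but its interferon list exceeded its housekeeping list by 4.06 on the log2 scale relative to the other SOD1-G85R samples. The genotype alone is argued against by those samples, whose interferon median was 0.25 above WT. A swap of labels between the groups would make this sample a WT brain. Yet its log2 correlations with every other sample were 0.824 to 0.834, against 0.978 to 0.984 among WT samples. Its interferon median was 4.27 over the WT mean, against -0.11 to 0.09 in the WT samples. These values argue against a swap as the reason why the sample stands apart. A swap would also need a WT sample out of place. The WT sample closest to SOD1-G85R replicates 1 and 3, WT replicate 3, had a mean correlation with the other WT samples only 0.0035 higher than with those 2, against a range of 0.0059 among WT pairs. That does not decide whether labels were swapped, and earlier tests on other correlations were dropped because they could not have decided it either. Another wrong label, a sample from outside the series, or an infection or other condition of that animal may account for this sample. They stay open, since no treatment or health record is given in the labels.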

How the results depend on the processing

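The term for Uty signal, the common floor of 20 and the fits without SOD1-G85R replicate 2 that add another change were chosen after the data were seen, and so was the choice to follow the 4 lists called with and without that sample. None of the 20 genes named by the rule and none of the 9 called lists changed direction in its test under the alternatives run. For the genes this is no separate evidence. They were picked for groups that did not overlap, so leaving out a sample could not reverse them. The filter at 50 kept only 10 of the 20. The cell cycle list's median was -0.15 after quantile normalization, although its test still gave higher. Quantile normalization shrank 13 of the 20 log2 fold changes by over 1.5 times, most of all Lta from 1.07 to 0.17, and the common floor of 20 shrank 8. Among lists not called, microglia and macrophage markers and endothelial markers turned from higher to lower without SOD1-G85R replicate 2. Endothelial markers also turned when centred on medians, and the ubiquitin and autophagy list turned from lower to higher after quantile normalization. The planned tests for raw counts were not run because the values are scaled, and those of Sod1 were not run. Genes past an adjusted p of 0.05 numbered 0 to 10 when each replicate was left out, the 10 coming without SOD1-G85R replicate 2. They numbered 52 with sample weights, whose estimate stopped short of its convergence tolerance, 4 at an adjusted p of 0.10 and 116 at an unadjusted p of 0.05, and 0 under the other alternatives. Called lists numbered 3 (without WT replicate 2) to 12 when each replicate was left out, 5 without the filter, 4 with sample weights, 0 with fry in 1 direction, 6 with fry in either direction, and 0 with an estimated correlation, with or without SOD1-G85R replicate 2. Without that sample and with the Uty term they numbered 4, but there 1 WT sample alone stood against 2, so that fit supports nothing. The median of all genes ran from 0.0071 (without SOD1-G85R replicate 2) to 0.26 with each replicate left out, and was -0.059 when centred on medians and -0.083 after quantile normalization. With an estimated correlation the adjusted p was 0.413 for the myelin, glutamate and lymphocyte lists and 0.612 for the cell cycle list, and without SOD1-G85R replicate 2 it was 0.632 for all 4. With fry it was 0.184 for myelin and 0.0904 for the other 3. The cell cycle list had 0.00766 to 0.126 with each replicate left out, 0.183 when centred on medians, 0.838 after quantile normalization, 0.0622 without the filter and 0.114 with the Uty term, and the lymphocyte list 0.185 after quantile normalization. The filter at 50 left too few lymphocyte genes for a test. Of the other 5 called lists, apoptosis passed in 10 of 23 alternatives, interferon and reactive astrocytes in 11 each, and the pan-neuronal and cytoskeleton lists in 13 each. Except where fewer samples entered, the cause was not tested. Same-numbered samples had correlations of deviations of 0.23, 0.09 and 0.10, against -0.32 to 0.19 between samples of different numbers. With 3 pairs, these values neither show nor exclude a pairing. The replicate block gave 0 genes, 162 at an unadjusted p of 0.05 against 116 without it, and 7 lists. Depth limits genes near the floor, where WT means under 30 rest on few counts.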

Other observations

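The tests of the Uty term, of the fit without SOD1-G85R replicate 2 and of scaling near background were chosen after the results they bear on had been seen. In SOD1-G85R replicate 2, 23 of 24 microglia and macrophage markers, 11 of 12 disease-associated microglia markers and 10 of 17 homeostatic microglia markers lay above both other SOD1-G85R samples. The genes that follow were chosen after their values were seen. Tmem119, a homeostatic marker, was at 514 there against 170 and 239 in those samples. P2ry12, a receptor of resting microglia, was at 302 there and at 476 and 692 in the other SOD1-G85R samples, with a WT mean of 812 ± 242. Fcrls was at 70.1 there against 272 and 300, while the complement gene C3 was at 1422 against 41.5 and 68.2 and the antigen presentation gene Cd74 at 5030 against 91.6 and 158. Srxn1, an antioxidant gene, averaged 638 ± 51.9 in WT and 423 ± 37.8 in SOD1-G85R, and the neuronal chemokine gene Cx3cl1 averaged 2113 ± 185 and 1387 ± 161, neither passing limma's threshold.

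In the deposited scaling the myelin list was called lower and the cell cycle list higher in SOD1-G85R, but neither with an estimated correlation (camera, adjusted p = 0.413 and 0.612). The cell cycle median was 0.05 with samples centred on their medians and -0.15 after quantile normalization, so scaling stays open for it. Without the sample that stands apart the medians were -0.87 and 0.25, and both lists were called (camera, adjusted p = 0.632 each with an estimated correlation). Both were followed because they were called with and without that sample, so these calls are no separate evidence. Against the WT mean, SOD1-G85R replicates 1 and 3 had myelin medians of -1.17 and -0.47 and cell cycle medians of 0.14 and 0.36. The medians thus do not rest on replicate 2 alone, but given that selection they are no test of it. For the myelin genes a Uty term, as a reading of the sex of the animals, gave a median of -0.65. The only SOD1-G85R sample with Uty signal was replicate 2, so the term mixes sex with that sample's difference and cannot decide. Every SOD1-G85R sample lay below every WT sample for this list, with or without Uty signal. For the cell cycle genes sex stays open as well. Their median was 0.26 with and without the term, but with it the call was lost (camera, adjusted p = 0.114). The median SE of the members was 0.24 without the term and 0.27 with it, and the median of all genes 0.15 and 0.17. Why the call was lost was not tested. The myelin fit replaced a comparison among the samples without Uty signal, which gave -0.91 but held 1 WT sample. A less mature brain in the SOD1-G85R samples may account for both, as a hypothesis: 6 of 6 genes of immature neurons and progenitors outside both lists (Sox4, Stmn1, Dlx1, Dlx2, Cd24a and Islr2) had a positive fold change without SOD1-G85R replicate 2, with a median of 0.34, and none passed limma's threshold. Whether age, litter or genotype would underlie it was not tested.

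Low-signal lymphocyte and granulocyte markers were called higher in SOD1-G85R as deposited, but not with an estimated correlation (camera, adjusted p = 0.413) or after quantile normalization (adjusted p = 0.185, median 0.43), and the call could come from scaling. On the count scale the list's difference between SOD1-G85R replicates 1 and 3 and WT was 0.46, against 0.95 as deposited, and the steps themselves differed by 0.52. Over the whole panel, 644, 675 and 660 genes were above 20 in the WT samples, against 709, 734 and 744 in the SOD1-G85R samples. The low end of the panel thus differed between the groups, whatever the function of the genes. Low-signal genes of the apoptosis, cell cycle and chromatin lists, 13 in number, were 0.75 higher, against 1.17 for the low-signal lymphocyte genes. Members of both sets had low WT means and had passed the low-value filter. A gene under the filter's threshold in every WT sample passed only if every SOD1-G85R sample exceeded it. Such selection favours genes higher in SOD1-G85R and can raise both values, by an amount that was not tested. Neither this comparison nor that on the count scale decides. Scaling near background and a rise of all low-signal genes thus cannot be told apart from more lymphocytes.

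The 6 samples make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 116 genes at an unadjusted p of 0.05 and the highest other 82, so that 1 of 10, the real split itself, gave as many. It gave 0 genes past an adjusted p of 0.05, a level reached by all 10 splits, with 2 genes in the highest other. For called lists, 3 splits gave at least the real 9, and the highest other gave 12. For the size of the myelin median, 1 split gave as much, with 0.71 in the real split and 0.59 in the highest other.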
